A study of Mus musculus with 24 samples.

How the data were processed

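RNA from mouse heart pieces was hybridised to 24 two-colour Agilent arrays, 1 per piece, against RNA pooled from whole pups. Per the labels, the heart channel is Cy5 and the reference Cy3 on every array, with no dye swap, and 50 ng of RNA was amplified and labelled. A labelling protocol text names Cy3-CTP for the heart RNA, while the label and source fields name Cy5. Ratios were therefore taken as Cy5 over Cy3, and dye bias cannot be separated from the ratio itself but, for the same probe, cancels in differences between arrays.

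Per the file headers, the scanner images were read with Feature Extraction 9.5.3.1, which gives the intensity of each spot in both channels, a local background, flags and a log10 ratio. The deposited intensity values are mean spot signals and background medians on a linear scale and are not normalized. The deposited log10 ratio is Agilent's, red over green, after its own background subtraction and dye normalization per the file headers. The value table deposited for the series holds log2 ratio values whose scale was found by setting each column against that array's own ratios (correlation at least 0.986, Cy5 over Cy3). How the authors centred that table is not given in the sources used here. The time from release of the artery to harvest is not given either.

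Background was corrected with normexp (offset 50) on mean signals with the local background median, and ratios were normalized by loess within each array, with control and outlier-flagged spots at weight 0, in limma 3.58.1 under R 4.3.3. The offset pulls ratios of dim spots toward 0, so fold changes of dim genes are understated. Duplicate spots of a probe were averaged and outlier-flagged spots left out. Of 41174 probes, 15412 were kept because their Cy5 spot was well above background on all arrays of at least 1 group. Each gene was represented by its probe with the highest mean Cy5 signal, which gave 11419 features. No spot was saturated. Symbols were updated through a RefSeq gene table of another build than the array's, used for names only: 22951 probes matched by accession and 18223 did not and kept the array's name unless an older symbol could be updated (3109 probes). No coordinates are printed because the array's genome build is not named.

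Groups were taken from the sample labels: genotype, surgery and piece. The arrays sat on 7 slides. No 2 arrays held identical values, and correlations between arrays ran from 0.565 to 0.983. All 24 arrays entered 1 limma fit (lmFit and eBayes) of 8 group means, with 16 residual degrees of freedom, so that groups of 3 shared 1 estimate of the spread. The 2 pieces of a heart entered as separate arrays without a term for the heart. A result seen in both pieces is therefore not 2 independent results. The median within-group SD was 0.098 on sham and 0.19 on I/R arrays. The shared estimate is therefore often too wide for differences between sham groups and too narrow for those between I/R groups. Tg+ was compared with wild type in each surgery and piece, I/R with sham in each genotype and piece, and below with above in each surgery. Both interactions were tested in the same fit. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and 0.05 was the threshold. Values after ± in the report are standard errors of the fit unless given as SD, and log2 changes without a p passed the threshold unless stated. Where a gene was not well above background on any array of a group, its fold is a lower bound set from the dimmest probes that were above background, and is open to dye bias, which need not cancel between different probes.

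Before the data were examined, 31 gene lists were written from textbook knowledge, among them markers of the cell types that a heart piece could hold. Of these, 29 had at least 5 tested genes and went through camera with a preset correlation of 0.01, which made 377 tests adjusted together. In that form 118 passed, 79 upward and 39 downward, and none passed when the correlation between genes was estimated. Lymphocyte markers (2 tested genes) and thymus and airway markers (4) were not tested as lists. Genes were named by a rule fixed beforehand. It takes Trim63, then in each comparison the 8 largest increases and 8 largest decreases past the threshold (4 and 4 for interactions), and up to 4 members of each list that passed or had 2 or more members past the threshold. Where nothing passed, the 3 genes with the smallest p were named. A gene that the rule names is not reported here.

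Alternatives fixed beforehand were no background correction, Agilent's log ratio, Aquantile between arrays, the Cy5 channel alone, no filter on dim probes, slide as a block, the replicate number or heart as a block, only the arrays of a comparison, array weights, the series value table, the mean of all probes, and each array left out in turn. Aquantile leaves the ratio within each array as it is, so it cannot change a call. Leaving out the 5 arrays with under 25% of Cy5 spots well above background, and keeping only the 3231 features above background on all arrays, were added after the data had been seen. The fit was tested on simulated data with 200 changed genes among 11419, drawn without slide effects. Each simulated gene had the same spread on all arrays, so the wider spread of the I/R arrays and their weak signal were left out. The shares recovered need not hold for the real comparisons. In the simulated genotype comparison of sham hearts above the site, 47.8% of genes changed by 0.5 on the log2 scale were recovered, 92.5% of those changed by 1 and 98.5% of those changed by 2. In the simulated interaction above the site the shares were 13.4%, 61.2% and 95.5%.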

Results

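The series measured transcript levels in hearts of mice labelled wild type and MuRF1 Tg+. MuRF1, encoded by Trim63, is a muscle ubiquitin ligase that sits at the sarcomere. Wild-type and MuRF1 Tg+ mice, 12 to 16 weeks old, had sham surgery or ischemia-reperfusion (I/R), in which the left anterior descending coronary artery is tied and later released. Tissue above and tissue below the tie, or below the site where it would have been placed, went onto separate two-colour arrays. This gave 8 groups of 3 arrays and 24 arrays in all. Heart RNA carried Cy5, and a Cy3-labelled pool of whole day 1 pups was the common reference on every array. The labels give 3 biological replicates per genotype and surgery, with 2 pieces from each heart. The number of arrays limits the precision of every value below.

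The heart channel was weaker on part of the I/R arrays. On sham arrays 34.6% to 43.3% of Cy5 spots were well above background (mean 37.9% ± 2.93 SD, n = 12). On I/R arrays the range was 9.90% to 38.3% (mean 27.0% ± 10.3 SD, n = 12), while the reference channel lay between 39.5% and 51.3%. Under 25% of the Cy5 spots passed on 5 arrays, all from I/R hearts. These were wild-type above replicates 1 and 2, wild-type below replicate 1, and Tg+ below replicates 2 and 3. Of the variance over the tested genes, 60.5% lay on the first principal component. Its highest scores were on Tg+ below replicates 2 (53.3) and 3 (44.9), wild-type below replicate 1 (50.9) and wild-type above replicate 2 (36.9). These I/R arrays had the lowest Cy5 shares (13.5%, 20.1%, 9.90% and 15.7%). Wild-type I/R below replicates 2 and 3, at 38.3% and 37.9%, scored -11.0 and -10.5, near the sham arrays (-25.4 to -12.5). The median within-group SD of the log2 ratio was 0.098 on sham arrays and 0.19 on I/R arrays.

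**Figure D1:**
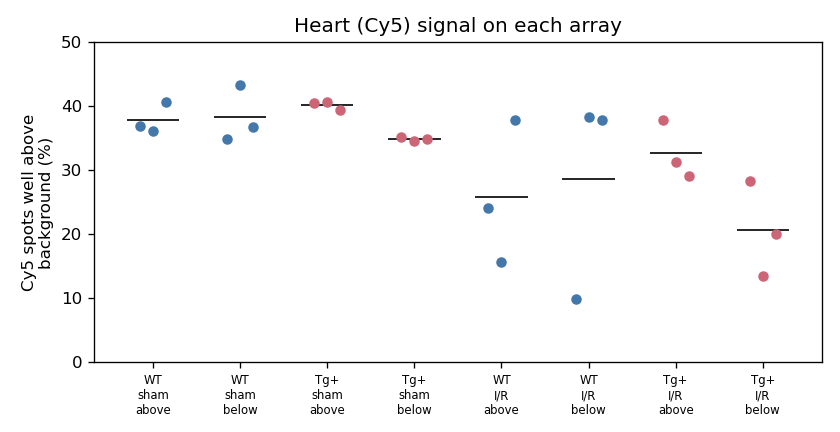
Percent of Cy5 (heart) spots well above background on each array, by group, with 1 point per array (wild type blue, Tg+ red) and a line at the group mean (n = 3). All 12 sham arrays lie between 34.6% and 43.3%, and 5 of the 12 I/R arrays lie under 25%.

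Trim63 was measured first, since the transgene defines the genotype. Its bright probe was well above background on all 24 arrays. In sham hearts the log2 ratio above the site was 2.34 ± 0.13 (SD, n = 3) in wild type and 2.36 ± 0.09 in Tg+, and below it was 2.35 ± 0.17 and 2.28 ± 0.10. The Tg+ minus wild-type difference was 0.03 ± 0.39 (SE) above (limma adjusted p = 1.00) and -0.07 ± 0.39 below (adjusted p = 1.00). Each SE here comes from 1 spread shared by all 8 groups. After I/R the group SD was 0.26 above and 1.08 below in wild type, and 0.48 and 0.77 in Tg+. The shared SE therefore overstates the spread of the sham differences and understates that of the difference below after I/R. After I/R the differences were 0.09 ± 0.39 above (adjusted p = 0.937) and -0.90 ± 0.39 below (adjusted p = 0.164). The last value passed the threshold without wild-type I/R below replicate 1 (-1.53, adjusted p = 0.00128) and without Tg+ I/R below replicate 1 (-1.35, adjusted p = 0.0240). A dimmer Trim63 probe, above background on 10 arrays, gave differences of -0.08, -0.05, 0.07 and 0.17 in the same order, none past the threshold. Whether either probe lies inside the transgene is not given in the sources used here, so these values do not check the genotype labels.

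**Figure D2:**
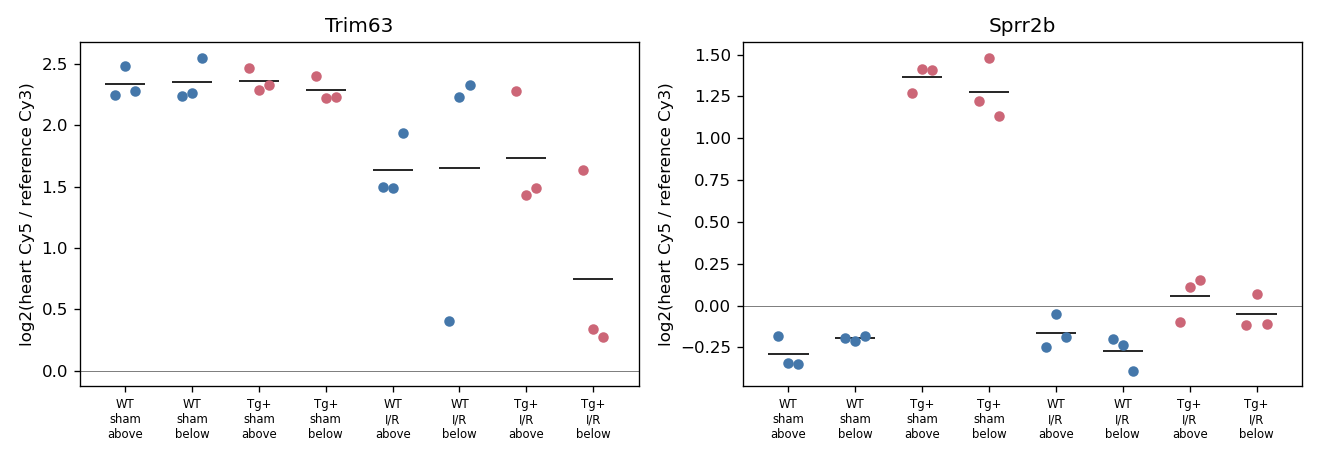
Log2 ratio of heart Cy5 to reference Cy3 for Trim63 (left) and Sprr2b (right) on each array, by group (wild type blue, Tg+ red), with a line at the group mean (n = 3). Trim63 does not separate Tg+ from wild type in sham hearts, while Sprr2b is 1.13 or higher on all 6 Tg+ sham arrays and 0.15 or lower on all other arrays.

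The first comparison set hearts labelled Tg+ against wild type without injury. Sprr2b and Sprr2k, small proline-rich proteins of the cornified envelope of skin, rose in Tg+ sham hearts. Above the site Sprr2b was 3.15-fold higher (log2 1.65 ± 0.10, adjusted p = 4.44e-09) and Sprr2k 2.06-fold (log2 1.04 ± 0.08, adjusted p = 1.37e-07). Below it the log2 differences were 1.47 ± 0.10 (adjusted p = 3.49e-08) and 0.84 ± 0.08 (adjusted p = 5.52e-06). Sprr2 genes are near-identical paralogs, so which of them the probes measure is uncertain. Top1mt, the mitochondrial topoisomerase, fell above the site (-0.42 ± 0.06, adjusted p = 0.00781). An Ensembl transcript without a gene symbol, ENSMUST00000035300, fell by 1.22 ± 0.21 on the log2 scale above (adjusted p = 0.0480) and fell by 1.29 ± 0.21 below (adjusted p = 0.0312). It was named after its values were seen, and its call was lost whichever of the 6 arrays was left out in either piece (adjusted p up to 0.580 above and 0.292 below).

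In all, 4 of 11419 features passed above the site (2 higher, 2 lower) and 3 below (2 higher, 1 lower). At an unadjusted p under 0.05 the counts were 227 and 167. Both are below a share of 0.05 of the 11419 features, the share that would pass with no difference, so they are no sign of further changes. No member of the sarcomere list passed on its own, and its 27 members had medians of 0.19 above (0 higher and 0 lower adjusted over the list alone, adjusted p = 0.00658, and adjusted p = 0.401 with an estimated correlation) and 0.17 below (0 higher and 0 lower adjusted over the list alone, adjusted p = 0.00148, and adjusted p = 0.312 with an estimated correlation). The ubiquitin proteasome and atrophy list, 26 members, had medians of 0.08 above (0 higher and 0 lower adjusted over the list alone, adjusted p = 0.00275, and adjusted p = 0.312 with an estimated correlation) and 0.07 below (0 higher and 0 lower adjusted over the list alone, adjusted p = 0.0459, and adjusted p = 0.486 with an estimated correlation). Monocyte and macrophage markers had a median of -0.14 above (0 higher and 0 lower adjusted over the list alone, adjusted p = 0.00226, and adjusted p = 0.632 with an estimated correlation) and endothelial markers -0.18 (0 higher and 0 lower adjusted over the list alone, adjusted p = 0.00929, and adjusted p = 0.712 with an estimated correlation). No slide held both genotypes of 1 condition, and with slide as a block 2 features passed in each piece while the mean sarcomere shift above went from 0.18 to -0.0041 and that below from 0.16 to 0.27. The mean ubiquitin proteasome shift went from 0.08 to 0.03 above and from 0.06 to 0.09 below with that block. Above, endothelial markers went from -0.16 to -0.09 and macrophage markers from -0.14 to -0.11. Counts above were 2 without wild-type sham above replicate 1, 2 without wild-type sham above replicate 3 and 2 without Tg+ sham above replicate 2, and Top1mt lost its call in 3 of these 6 fits (largest adjusted p = 0.102).

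In wild-type hearts above the site the metallothionein Mt2 was 28.6-fold higher after I/R (log2 4.84 ± 0.75, adjusted p = 0.000586) and Mt1 rose by 2.52 ± 0.49. The Mt2 ratio was 1.003 and 3.675 on the weak-signal I/R replicates 1 and 2 and 1.745 on replicate 3, against a sham mean of -2.7. S100a9, a neutrophil calcium-binding protein, rose by 4.00 ± 0.69 (adjusted p = 0.00128), and the macrophage protein Chil3 by 2.54 ± 0.35 (adjusted p = 0.000228). The S100a9 ratio was -0.83 and 0.24 on the weak-signal replicates 1 and 2 and -2.64 on replicate 3, against a sham mean of -5.07. Pdk4, which restrains pyruvate oxidation, rose by 2.66 ± 0.70, Angptl4, an inhibitor of lipoprotein lipase, by 2.45 ± 0.64, and the matrix protein Ccn2 by 2.16 ± 0.53. Sln, an atrial regulator of the calcium pump, rose by 4.06 ± 1.13 (adjusted p = 0.0231), a call lost in 4 of 6 fits that left out an array. The largest falls were in cardiac actin Actc1 (-1.88 ± 0.31), Fyco1 (-1.75 ± 0.31), the ketone enzyme Oxct1 (-1.64 ± 0.34), the thin-filament protein Lmod3 (-1.60 ± 0.19), Efcab2 (-1.57 ± 0.46, with another probe going the other way), Tuba4a (-1.53 ± 0.21), Lrtm1 (-1.42 ± 0.40) and Asb10 (-1.37 ± 0.40). The calls of Efcab2 and Lrtm1 were lost in 4 of these 6 fits, that of Asb10 in 5, that of Angptl4 in 3 (adjusted p up to 0.108), that of Pdk4 in 2 (up to 0.111) and that of Ccn2 in 1 (up to 0.0747).

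Of 17 genes for inflammatory cytokines and adhesion 10 rose and none fell, with a median of 0.92 (12 higher and 1 lower adjusted over the list alone, adjusted p = 2.08e-07, and adjusted p = 0.312 with an estimated correlation). Cebpd rose by 2.08 ± 0.22, Cebpb by 1.58 ± 0.21 and Socs3 by 1.00 ± 0.12. Glucocorticoid response genes rose in 7 of 16 cases and fell in 1 (10 higher and 1 lower adjusted over the list alone, adjusted p = 0.000267, and adjusted p = 0.312 with an estimated correlation). Monocyte and macrophage markers rose in 6 of 21 cases (10 higher and 0 lower adjusted over the list alone, adjusted p = 1.2e-05, and adjusted p = 0.401 with an estimated correlation), among them Lgals3 (1.09 ± 0.17) and Mrc1 (0.57 ± 0.13). Neutrophil markers rose in 3 of 7 cases (5 higher and 0 lower adjusted over the list alone, adjusted p = 0.000613, and adjusted p = 0.391 with an estimated correlation). Of the circadian clock list 4 of 14 fell and 1 rose (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.0211, and adjusted p = 0.566 with an estimated correlation). Tef (-1.02 ± 0.14) and Dbp (-1.18 ± 0.24) were among those that fell, and Nfil3 (0.90 ± 0.20) rose. Among 16 endothelial markers 4 fell (0 higher and 4 lower adjusted over the list alone, adjusted p = 0.0534, and adjusted p = 0.78 with an estimated correlation). Among them were the VEGF receptor Kdr (-1.26 ± 0.21) and Tek (-0.44 ± 0.09). Epicardial and mesothelial markers rose in 5 of 7 cases (6 higher and 0 lower adjusted over the list alone, adjusted p = 0.00107, and adjusted p = 0.528 with an estimated correlation). Among them were Msln (1.58 ± 0.35) and Aldh1a2 (0.68 ± 0.15). Atrial cardiomyocyte markers rose in 3 of 12 cases (6 higher and 0 lower adjusted over the list alone, adjusted p = 0.0186, and adjusted p = 0.722 with an estimated correlation). In total 1520 features passed, 683 higher and 837 lower. With slide as a block 259 passed, of which 204 were among the 1520 in the same direction. The mean inflammatory shift with it was 0.70 against 0.83, and 0.65 on the slide with 1 array of each group. Without the 5 weak-signal arrays 836 rose and 628 fell, with 809 of the 1520 shared, 796 features passed with only these 6 arrays in the fit, and leaving out 1 array gave 896 without wild-type sham above replicate 1, 786 without wild-type sham above replicate 2, 933 without wild-type sham above replicate 3 and 760 without wild-type I/R above replicate 2.

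**Figure D3:**
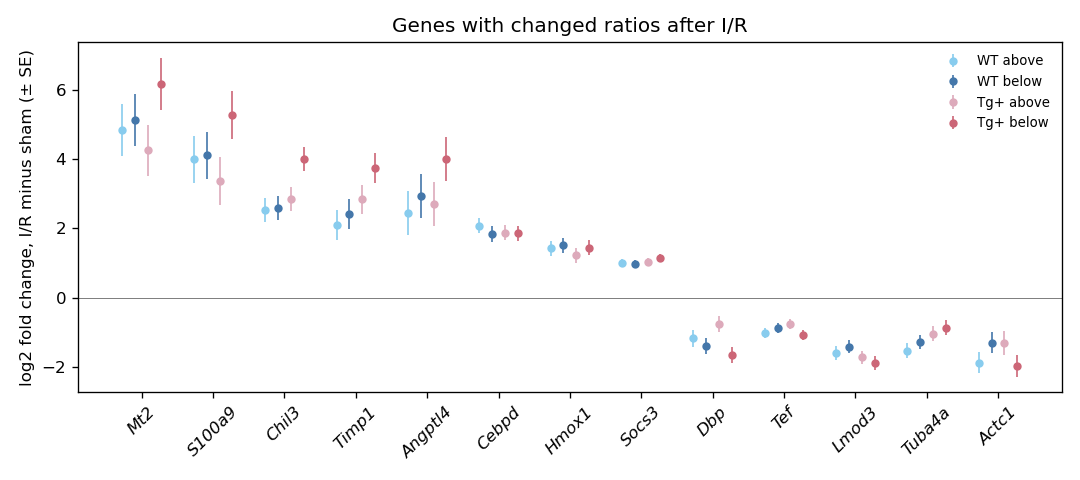
Log2 fold change from sham to I/R (± SE of the limma fit, n = 3 against 3 arrays) for 13 genes in wild-type and Tg+ hearts above and below the site. Mt2 and S100a9 rose most among the 13 in each comparison, and Actc1, Lmod3, Tuba4a, Dbp and Tef lie below 0 in all 4, while the Tg+ below point of Chil3 is a fitted value against sham arrays not well above background.

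Below the site in wild-type hearts Mt2 rose 35.1-fold (log2 5.13 ± 0.75, adjusted p = 0.00064), S100a9 by 4.11 ± 0.69 (adjusted p = 0.00228) and Chil3 by 2.59 ± 0.35. The Mt2 ratio was 4.826 on the weak-signal I/R replicate 1, but 1.355 and 1.286 on replicates 2 and 3, against a sham mean of -2.646. On the slide with 1 array of each group, neither of them weak, Mt2 rose by 3.865 and S100a9 by 3.669. The 35.1-fold value therefore draws on the weak-signal array. Fhl1, a LIM protein induced in hypertrophy, rose by 3.01 ± 0.56, Angptl4 by 2.94 ± 0.64, Mt1 by 2.61 ± 0.49 and the metalloproteinase inhibitor Timp1 by 2.42 ± 0.43. The S100a9 ratio was also higher on the weak-signal replicate 1 (0.83) than on replicates 2 and 3 (-1.72 and -1.625). Timp1 was lower there (0.50) than on replicates 2 and 3 (2.02 and 1.62). Lrtm1 (-1.63 ± 0.40), Lmod3 (-1.43 ± 0.19), the clock-output factor Dbp (-1.40 ± 0.24), titin (Ttn, -1.38 ± 0.40), Actc1 (-1.31 ± 0.31), Tuba4a (-1.29 ± 0.21), Lynx1 (-1.27 ± 0.36) and Fyco1 (-1.26 ± 0.31) fell. Leaving out an array ended the call of Ttn in all 6 fits (lowest adjusted p = 0.0556), those of Lrtm1 and Lynx1 in 4, that of Fyco1 in 3, that of Actc1 in 2 (adjusted p up to 0.0781) and that of Gbp3 in 1 (up to 0.0580). Inflammatory genes rose in 7 of 17 cases (10 higher and 0 lower adjusted over the list alone, adjusted p = 3.22e-08, and adjusted p = 0.312 with an estimated correlation). The chemokine Ccl2 was among them (1.29 ± 0.27). Neutrophil markers rose in 5 of 7 cases (5 higher and 0 lower adjusted over the list alone, adjusted p = 6.15e-06, and adjusted p = 0.312 with an estimated correlation) and oxidative stress genes in 7 of 22 (8 higher and 0 lower adjusted over the list alone, adjusted p = 1.27e-06, and adjusted p = 0.297 with an estimated correlation). Heme oxygenase Hmox1 was among them (1.51 ± 0.21). Interferon response genes had a median of -0.31 with 1 of 21 past the threshold, Gbp3 at -1.17 ± 0.24 (0 higher and 7 lower adjusted over the list alone, adjusted p = 1.34e-06, and adjusted p = 0.486 with an estimated correlation). In total 642 features passed, 244 higher and 398 lower, a share of 38.0% higher that became 50.5% of 317 features with Agilent's own log ratios. With only these 6 arrays in the fit none passed. A slide block left 25, all among the 642, with a mean inflammatory shift of 0.64 against 0.68, and 0.83 on the slide with 1 array of each group. Without the 5 arrays of weak Cy5 signal 1343 passed, 565 of them among the 642, and leaving out 1 array gave 279 without wild-type sham below replicate 1, 277 without wild-type sham below replicate 2 and 263 without wild-type sham below replicate 3.

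In Tg+ hearts above the site Mt2 (4.26 ± 0.75), S100a9 (3.37 ± 0.69), Ccn2 (3.12 ± 0.53), Chil3 (2.85 ± 0.35), Timp1 (2.84 ± 0.43), Pdk4 (2.81 ± 0.70) and Angptl4 (2.70 ± 0.64) rose after I/R. The largest increase was in the atrial myosin light chain Myl7 (4.99 ± 1.47, adjusted p = 0.0285), a call lost in 4 of 6 fits that left out an array. Lmod3 (-1.73 ± 0.19), Efcab2 (-1.44 ± 0.46), Actc1 (-1.32 ± 0.35), Sprr2b (-1.31 ± 0.10), sarcospan (Sspn, -1.31 ± 0.30), Ppp1r12b (-1.26 ± 0.18) and Acad11 (-1.25 ± 0.24) fell, as did Atp2a1 (-1.35 ± 0.28), for which another probe went the other way. The Efcab2 call was lost in all 6 fits that left out an array (lowest adjusted p = 0.0510), that of Actc1 in 2 (up to 0.101), and those of Pdk4 and Sspn in 1 each (up to 0.0669 and 0.0526). Monocyte and macrophage markers rose in 13 of 21 cases (15 higher and 0 lower adjusted over the list alone, adjusted p = 2.05e-08, and adjusted p = 0.312 with an estimated correlation). Among them were Lgals3 (1.35 ± 0.17) and F13a1 (1.19 ± 0.23). Glucocorticoid response genes rose in 11 of 16 cases (12 higher and 1 lower adjusted over the list alone, adjusted p = 2.11e-07, and adjusted p = 0.297 with an estimated correlation). Ddit4 was among them (2.10 ± 0.29). Immediate early genes rose in 8 of 20 cases (14 higher and 0 lower adjusted over the list alone, adjusted p = 2.16e-07, and adjusted p = 0.438 with an estimated correlation). Among them were Junb (1.40 ± 0.24) and Maff (1.40 ± 0.18). Fibroblast markers rose in 5 of 16 cases (5 higher and 0 lower adjusted over the list alone, adjusted p = 0.0107, and adjusted p = 0.724 with an estimated correlation). Among them were decorin (Dcn, 1.71 ± 0.34) and Fbln1 (1.16 ± 0.24). Ventricular cardiomyocyte markers fell in 4 of 11 cases (0 higher and 4 lower adjusted over the list alone, adjusted p = 0.0163, and adjusted p = 0.361 with an estimated correlation). Among them were Fhl2 (-0.98 ± 0.22) and Irx4 (-0.83 ± 0.24), the latter lost in 4 of the 6 fits. Atrial markers rose in 3 of 12 cases (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.0103, and adjusted p = 0.712 with an estimated correlation). In total 1745 features passed, 793 higher and 952 lower, against 395 higher and 331 lower with Agilent's log ratios (54.4% higher, against 45.4%). A slide block left 359, 355 of them shared, with a mean macrophage list shift of 0.68 against 0.67, and 0.63 on the slide with 1 array of each group. None of the 5 weak-signal arrays is in this comparison. Without them the log2 changes were the same (r = 1 across genes), but the shared spread narrowed (median SE 0.089 against 0.127) and 4760 passed. Leaving out 1 array gave 720 without Tg+ sham above replicate 1, 746 without Tg+ sham above replicate 3, 866 without Tg+ I/R above replicate 2 and 684 without Tg+ I/R above replicate 3.

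In Tg+ hearts below the site Mt2 rose 72.3-fold (log2 6.18 ± 0.75, adjusted p = 3.5e-05), S100a9 by 5.28 ± 0.69 (adjusted p = 7.45e-05) and Angptl4 by 4.02 ± 0.64. The Mt2 ratio was 3.107 and 4.024 on the weak-signal I/R replicates 2 and 3 and 2.17 on replicate 1, against a sham mean of -3.076. The 72.3-fold value therefore draws on the weak-signal arrays. Chil3 was not well above background in the Tg+ sham arrays and was at least 15.2-fold higher (adjusted p = 2.54e-06). The slow myosin heavy chain Myh7 rose by 3.94 ± 0.76, Timp1 by 3.75 ± 0.43, Fhl1 by 3.59 ± 0.56 and Mt1 by 3.03 ± 0.49. The S100a9 ratio was 1.03 and 0.08 on the weak-signal replicates 2 and 3 and -0.87 on replicate 1, against a sham mean of -5.20. For Timp1 these ratios were 3.30, 3.49 and 1.78, against a sham mean of -0.89. The sizes of both increases therefore draw on the weak-signal arrays too. Phospholamban (Pln, -2.79 ± 0.69), Lrtm1 (-2.39 ± 0.40), Efcab2 (-2.32 ± 0.46), the mitochondrial phosphate carrier Slc25a3 (-2.16 ± 0.36), Oxct1 (-2.12 ± 0.34), the formin Fhod3 (-2.11 ± 0.40), Idh2 (-2.05 ± 0.50) and Perm1 (-2.04 ± 0.44) fell. Trim63 itself fell by 1.53 ± 0.39 on the log2 scale (adjusted p = 0.00711), while its dimmer probe gave -0.01. Without the 5 weak-signal arrays, which take out Tg+ replicates 2 and 3, the change was -0.65 (adjusted p = 0.0729), and with slide as a block it was -1.45 (adjusted p = 0.155).

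Of 26 calcium handling genes 12 fell and 1 rose (1 higher and 15 lower adjusted over the list alone, adjusted p = 0.00381, and adjusted p = 0.638 with an estimated correlation). Triadin (Trdn, -1.20 ± 0.17) and Jph2 (-1.97 ± 0.42) were among those that fell. Fatty acid oxidation genes fell in 13 of 29 cases and rose in 1 (2 higher and 13 lower adjusted over the list alone, adjusted p = 0.00882, and adjusted p = 0.72 with an estimated correlation), Hadhb (-1.18 ± 0.24) and Acadm (-1.33 ± 0.29) among those that fell. Oxidative phosphorylation genes fell in 12 of 34 cases (0 higher and 12 lower adjusted over the list alone, adjusted p = 0.0429, and adjusted p = 0.783 with an estimated correlation). Among them were Ndufa10 (-1.77 ± 0.26) and Sdhc (-1.16 ± 0.18). Of 27 sarcomere genes 10 fell and 3 rose (3 higher and 10 lower adjusted over the list alone, adjusted p = 0.125, and adjusted p = 0.712 with an estimated correlation). Of 11 ventricular markers 6 fell (1 higher and 7 lower adjusted over the list alone, adjusted p = 0.0319, and adjusted p = 0.418 with an estimated correlation). Myl3 was among them (-1.83 ± 0.40). Inflammatory genes rose in 12 of 17 cases (13 higher and 0 lower adjusted over the list alone, adjusted p = 5.11e-06, and adjusted p = 0.312 with an estimated correlation). Ccl2 was among them (1.66 ± 0.27). Matrix genes rose in 7 of 28 cases (7 higher and 0 lower adjusted over the list alone, adjusted p = 8.61e-05, and adjusted p = 0.712 with an estimated correlation). Mmp14 was among them (1.33 ± 0.36). Adipocyte markers rose in 6 of 10 cases (9 higher and 0 lower adjusted over the list alone, adjusted p = 0.00405, and adjusted p = 0.722 with an estimated correlation). Skeletal muscle markers rose in 5 of 11 cases and fell in 3 (7 higher and 3 lower adjusted over the list alone, adjusted p = 0.359, and adjusted p = 0.86 with an estimated correlation), the fast myosins Myh2 (1.97 ± 0.50) and Myh1 (1.47 ± 0.38) among those that rose. Tg+ I/R below replicates 2 and 3 had weak signal. On the slide that holds that replicate 2 and a sham array, mean shifts were 1.20 for skeletal muscle, 1.815 for adipocyte and 0.90 for erythroid markers. With all arrays they were 0.79, 1.29 and 0.25. Whether weak signal raised these ratios was not tested. In total 3699 features passed, 1746 higher and 1953 lower, against 1380 higher and 2255 lower with Agilent's log ratios (38.0% higher, against 47.2%). With a slide block 249 passed, all among the 3699. The mean fatty acid oxidation shift with it was -0.28 against -0.32, and -0.42 on the slide with 1 array of each group. That of oxidative phosphorylation was -0.18 against -0.28, and -0.14 on that slide. Without the 5 weak-signal arrays, which leaves 1 Tg+ I/R below array, 1547 passed and the fatty acid oxidation list lost its call (adjusted p = 0.858). Leaving out 1 array gave 2241 without Tg+ sham below replicate 1, 1874 without Tg+ I/R below replicate 2 and 1966 without Tg+ I/R below replicate 3. The calls of Mmp14 and Myh1 were lost in 1 of 6 such fits each (adjusted p up to 0.0758 and 0.0527).

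**Figure D4:**
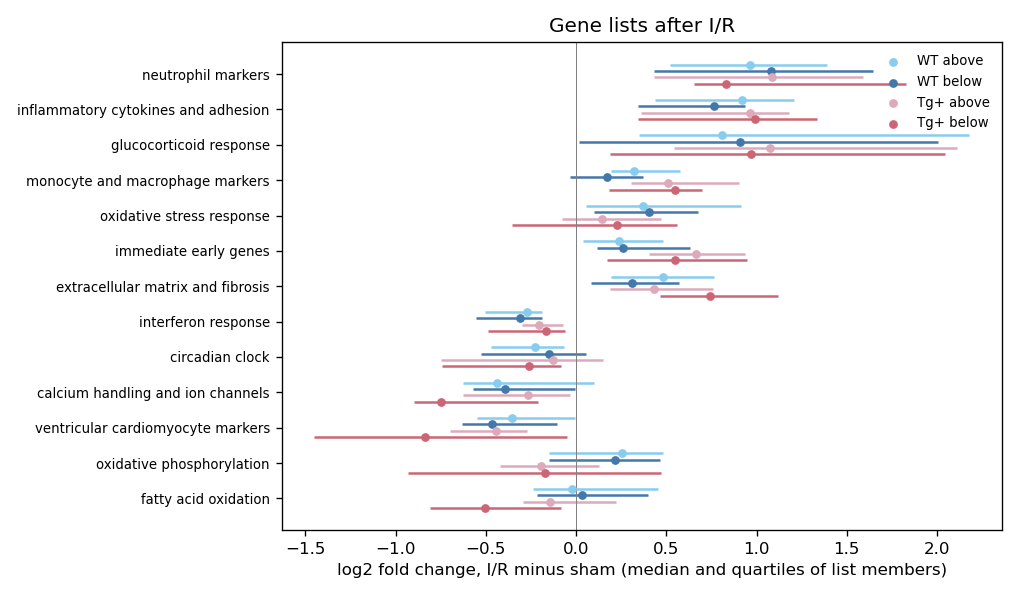
Median (point) and quartiles (line) of the log2 fold change from sham to I/R over the tested members of 13 gene lists, in wild-type and Tg+ hearts above and below the site. Neutrophil, inflammatory and glucocorticoid lists have medians above 0 in all 4 comparisons, and interferon, circadian and ventricular lists have medians below 0 in all 4.

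The wild-type and Tg+ responses shared many genes. Above the site 326 features rose in both genotypes (47.4 expected for independent lists), 400 fell in both (69.8 expected) and 4 went opposite ways. Below it 187 rose in both (37.3 expected), 316 fell in both (68.1 expected) and none went opposite ways. The log2 changes correlated across genes with r = 0.77 above and r = 0.78 below, where genes are not independent replicates and the 2 genotypes share no array. Both genotypes used the same spread for each gene, however, so genes of small spread pass more readily in both lists. The expected counts leave this out. Below the site the I/R groups of both genotypes also held weak-signal arrays, and their part in the overlap was not tested. The interaction asked whether the response differed by genotype. Only Sprr2b (-1.44 ± 0.13 above, adjusted p = 2e-05, and -1.25 ± 0.13 below, adjusted p = 0.000189) and Sprr2k (-0.93 ± 0.11 above, adjusted p = 0.000243, and -0.86 ± 0.11 below, adjusted p = 0.000781) passed. After I/R neither gene passed between genotypes. The Sprr2b difference was then 0.22 ± 0.10 above (adjusted p = 0.307, unadjusted p = 0.0349) and 0.22 ± 0.10 below (adjusted p = 0.163, unadjusted p = 0.0305), and the Sprr2k difference 0.11 ± 0.08 above and -0.03 ± 0.08 below. At an unadjusted p under 0.05 the interaction counts were 948 above and 1194 below. With slide as a block no interaction passed, as the standard errors grew and the differences changed little. Sprr2b was then -1.43 ± 0.20 above (adjusted p = 0.0671) and -1.15 ± 0.20 below (adjusted p = 0.312), and Sprr2k -0.94 ± 0.14 and -0.86 ± 0.14 with the same adjusted p. On the 1 slide per comparison with a sham and an I/R array, the Tg+ change of Sprr2b was -1.30 above and -1.07 below, against -0.07 and -0.21 in wild type, and that of Sprr2k -0.94 and -0.91 against 0.15 and 0.01. With Agilent's log ratios none passed either (Sprr2b -1.94 above, adjusted p = 0.547, and -1.77 below, adjusted p = 0.142), nor above the site with the Cy5 channel alone. Leaving out 1 array gave 4 without wild-type I/R above replicate 2, 6 without wild-type I/R above replicate 3 and 9 without Tg+ I/R above replicate 1 above and 2035 without wild-type I/R below replicate 1 and 359 without Tg+ I/R below replicate 1 below, and without the 5 weak-signal arrays the counts were 49 above and 13 below.

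After I/R above the site, Tg+ hearts had more of Fbxo2 (1.10 ± 0.23), the flow-responsive factor Klf2 (1.07 ± 0.24), the immediate early gene Ier5 (0.94 ± 0.20), the Hippo pathway coactivator Wwtr1 (0.81 ± 0.14), Akap13 (0.69 ± 0.16), Fmo2 (0.65 ± 0.14) and Mical2 (0.61 ± 0.13) than wild type, and of Tmem165 (0.80 ± 0.18), whose other probe went the other way. They had less of Rab5if (-1.15 ± 0.22), the mitochondrial ribosomal protein Mrpl3 (-0.98 ± 0.19), Dtnbp1 (-0.76 ± 0.12), Ctnnal1 (-0.76 ± 0.14), monoamine oxidase B (Maob, -0.75 ± 0.16), Arl4a (-0.70 ± 0.13) and Pdcd10 (-0.70 ± 0.16). Adjusted p-values of these genes lay between 0.0167 and 0.0489, and each call was lost in 3 to 5 of the 6 fits that left out an array. No oxidative phosphorylation gene passed, and the 34 members had a median of -0.48 (0 higher and 2 lower adjusted over the list alone, adjusted p = 5.11e-06, and adjusted p = 0.553 with an estimated correlation). Endothelial markers had a median of 0.38 (0 higher and 0 lower adjusted over the list alone, adjusted p = 1.14e-05, and adjusted p = 0.486 with an estimated correlation) with none past the threshold, and 2 of 20 immediate early genes were higher (3 higher and 0 lower adjusted over the list alone, adjusted p = 0.000162, and adjusted p = 0.638 with an estimated correlation). In total 75 features passed, 29 higher and 46 lower, and leaving out 1 array gave 1 without wild-type I/R above replicate 1, 8 without wild-type I/R above replicate 2, 506 without wild-type I/R above replicate 3, 155 without Tg+ I/R above replicate 1, 5 without Tg+ I/R above replicate 2 and 0 without Tg+ I/R above replicate 3. Under a slide block, with no slide holding both groups, 67 passed with the balance turned, 49 higher and 18 lower, 19 of them shared. When the 5 weak-signal arrays were left out 89 passed, 10 higher and 79 lower, 14 of them shared (r = 0.40 across all genes between the fits). With the Cy5 channel alone 17 passed (17.6% higher, against 38.7%), and none with only these 6 arrays in the fit. The mean endothelial shift was 0.80 with the slide block against 0.35, and 0.22 without wild-type I/R above replicate 1. That of the oxidative phosphorylation list was -0.65 against -0.47, and -0.24 without wild-type I/R above replicate 2. The list lost its call without the weak-signal arrays (adjusted p = 0.526). The mean shift of the immediate early genes was 0.31, with 0.54 without Tg+ I/R above replicate 1 and 0.13 without replicate 2.

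Below the site after I/R, Tg+ hearts had more of the nuclear RNAs Malat1 (1.93 ± 0.40) and Neat1 (1.81 ± 0.30), of Chil3 (1.60 ± 0.35), nonmuscle myosin Myh9 (1.54 ± 0.33), Clic1 (1.48 ± 0.34), Mical1 (1.34 ± 0.23), Rhoc (1.30 ± 0.33) and vimentin (Vim, 1.29 ± 0.33). They had less of the succinate dehydrogenase subunit Sdhb (-1.69 ± 0.32), Txlnb (-1.64 ± 0.39), Asb11 (-1.60 ± 0.40), Slc25a3 (-1.55 ± 0.36), Ptgds (-1.42 ± 0.32), the pyruvate dehydrogenase subunit Pdhb (-1.41 ± 0.19, adjusted p = 0.00225), Got1 (-1.34 ± 0.21) and Herpud1 (-1.32 ± 0.27). Oxidative phosphorylation genes were lower in 8 of 34 cases (median -0.59, 0 higher and 13 lower adjusted over the list alone, adjusted p = 6.49e-07, and adjusted p = 0.486 with an estimated correlation). Cyc1 was among them (-0.66 ± 0.14). Fatty acid oxidation genes were lower in 5 of 29 cases and higher in 1, the acyltransferase Cpt1b (0.64 ± 0.15), (1 higher and 11 lower adjusted over the list alone, adjusted p = 2.05e-05, and adjusted p = 0.553 with an estimated correlation). The 9 other cell type marker lists with at least 5 tested genes all had medians above 0, from 0.11 for smooth muscle and pericyte to 0.66 for adipocyte markers (0 higher and 0 lower adjusted over the list alone, adjusted p = 0.0479, and adjusted p = 0.783 with an estimated correlation). Their medians without the 5 weak-signal arrays ran from 0.04 for endothelial markers (0.37 with all arrays) to 0.63 for adipocyte markers, with 0.07 for erythroid (0.23), 0.13 for macrophage (0.24) and 0.29 for fibroblast markers (0.48). The mean adipocyte shift of 0.65 was 1.39 without wild-type I/R below replicate 1, 0.21 without replicate 2 and 0.35 without replicate 3, and 1.04 and 0.34 without Tg+ I/R below replicates 1 and 2. All 3 Tg+ arrays and 1 of the 3 wild-type arrays here had fewer Cy5 spots above background than any sham array (28.3%, 20.1% and 13.5%, and 9.90%). In total 314 features passed, 131 higher and 183 lower. With the 5 weak-signal arrays left out 884 passed, 532 higher and 352 lower, with 92 of the 314 shared, and none passed with slide as a block or with only these 6 arrays in the fit. The count was 5219 without wild-type I/R below replicate 1, 4 without wild-type I/R below replicate 2, 14 without wild-type I/R below replicate 3, 1898 without Tg+ I/R below replicate 1, 4 without Tg+ I/R below replicate 2 and 4 without Tg+ I/R below replicate 3, and of the 16 leading genes only Pdhb passed whichever array was left out. The calls of Cyc1 and Cpt1b were each lost in 4 of these 6 fits (adjusted p up to 0.210 and 0.223). The mean fatty acid oxidation difference was -0.47 with all arrays, -0.46 with slide as a block and 0.05 without the 5 weak-signal arrays, and that of oxidative phosphorylation was -0.52, -0.34 and -0.19, and -0.27 without wild-type I/R below replicate 1 alone.

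The 2 pieces were then compared. In sham hearts no feature differed between below and above (0 of 11419 in limma, 58 at an unadjusted p under 0.05), and the genes with the smallest p were Nsmce2 (-0.17 ± 0.06), Tab3 (0.13 ± 0.05) and Klf12 (0.15 ± 0.06). In I/R hearts Myl7 was lower below (-5.61 ± 1.04, adjusted p = 0.0287), as were matrix Gla protein (Mgp, -1.49 ± 0.17, adjusted p = 0.000489), Fbln1 (-1.13 ± 0.17), Cytl1 (-0.87 ± 0.13), Cfhr2 (-0.75 ± 0.15), Pi16 (-0.72 ± 0.14) and Aldh1a1 (-0.65 ± 0.11). Neat1 (1.30 ± 0.22), the actin-binding protein Xirp2 (0.86 ± 0.17), Rras2 (0.85 ± 0.13), the uridine kinase Uck2 (0.82 ± 0.16), CTP synthase (Ctps, 0.55 ± 0.09), Gpatch4 (0.54 ± 0.07), Pacsin3 (0.52 ± 0.08) and Pisd (0.45 ± 0.09) were higher below. The 12 atrial cardiomyocyte markers had a median of -0.74 in I/R hearts, with 1 past the threshold over all genes (0 higher and 8 lower adjusted over the list alone, adjusted p = 2.05e-08, and adjusted p = 0.312 with an estimated correlation). In sham hearts their median was -0.13 (0 higher and 0 lower adjusted over the list alone, adjusted p = 0.00754, and adjusted p = 0.712 with an estimated correlation). In total 20 features passed in I/R hearts, 9 higher and 11 lower, and the difference between I/R and sham passed for none (427 at an unadjusted p under 0.05), Mgp coming closest (-1.30 ± 0.24, adjusted p = 0.21). The unadjusted counts of 58 and 427 are both below a share of 0.05 of the 11419 features. With only the I/R arrays in the fit none passed. With a slide block 4 passed in I/R hearts and the mean atrial shift was -1.38 against -1.41. Without the 5 weak-signal arrays 382 passed (18 shared), and 248 differed between I/R and sham. Myl7 lost its call in 9 of the 12 fits that left out an array, Xirp2 and Uck2 in 8, Cfhr2 and Pisd in 7 and Pi16 in 6, and the count was 58 without wild-type I/R below replicate 1, 84 without wild-type I/R above replicate 2, 250 without Tg+ I/R below replicate 1 and 11 without Tg+ I/R below replicate 2.

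**Figure D5:**
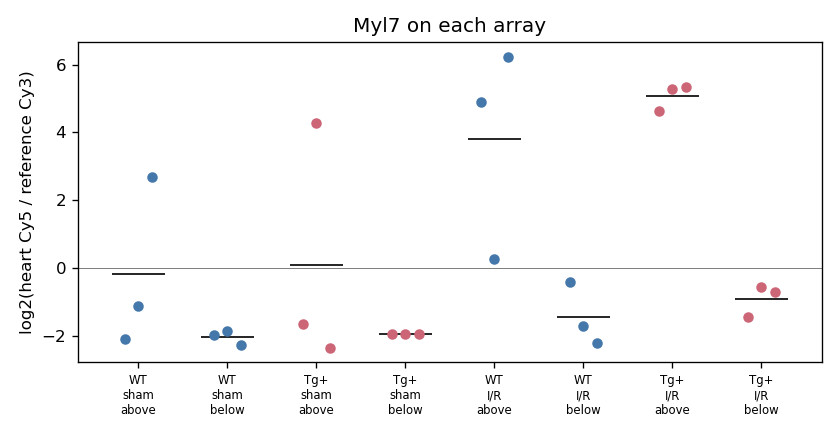
Log2 ratio of heart Cy5 to reference Cy3 for Myl7 on each array by group (wild type blue, Tg+ red), with a line at the group mean (n = 3). All 12 arrays of pieces below lie under 0, while pieces above reach from -2.35 to 6.23.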

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

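Exchanged labels, an absent genotype and the weak-signal arrays left out were tested, and the splits were sorted by genotype, only after the values had been seen, while the matched-signal test and the splits were set after the pattern was seen but before their own values were computed. The difference in surgery response between genotypes passed the interaction test for 2 genes in both pieces: for Sprr2b it was -1.44 above and -1.25 below, and for Sprr2k -0.93 above and -0.86 below. Labels exchanged between wild-type and Tg+ I/R hearts would give high Sprr2b ratios on wild-type I/R arrays only if Tg+ hearts keep the transcript after I/R. The highest Sprr2b ratio on any of the 6 wild-type I/R arrays was -0.0490 and the lowest on the 6 Tg+ sham arrays 1.13 (SD 0.14). The highest on the 6 Tg+ I/R arrays was 0.15, so exchanged labels cannot be told apart if I/R itself removes the transcript. Weak heart signal is argued against: without the 5 weak arrays the smallest of the 4 differences was -0.86. In the matched-signal test, however, where all 4 falls had to rank under the 2.5 percentile of 200 features, they ranked at 0 and 0.5 above and 1.5 and 4 below. That test, set before its values were computed, was therefore not met, and the argument rests on the fit chosen afterwards. On the 4 Tg+ I/R arrays that were not weak Sprr2b was at most 0.15 and Sprr2k at most 0.28, against at least 1.13 and 0.85 on the Tg+ sham arrays. Their Cy5 shares were 37.9%, 31.3% and 29.15% above and 28.3% below, against at least 34.6% on sham arrays. Tg+ I/R hearts that lack the genotype of the Tg+ sham hearts stay open: 0 of the 3 features called in both sham pieces was called in both I/R pieces, but after I/R Sprr2b was 0.22 higher in Tg+ in both pieces (adjusted p = 0.307 above and 0.163 below, unadjusted p = 0.0349 and 0.0305), ENSMUST00000035300 was -0.78 below (adjusted p = 0.0541) and Top1mt -0.18 above (adjusted p = 0.202), and a loss of the transcripts through I/R itself was not tested.

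Among 100 splits of the surgery labels within each genotype, 15 gave as many interaction calls as the 2 above (highest other 1114) and 10 as the 2 below (highest other 4438). Apart from the real split, 9 of these above and 8 below kept the real grouping of the Tg+ arrays, and the other 5 and 1 kept that of the wild type. The former carry the whole surgery difference of Tg+ hearts, in which 1745 features passed above and 3699 below, the Sprr2 fall among them. The counts of 15 and 10 splits therefore do not test chance. Of the splits that kept the real grouping of neither genotype, 0 of 81 above and 0 of 84 below gave as many calls (highest 0). Those splits mix sham and I/R arrays in both genotypes, so the surgery differences widen the spread and make calls less likely. They do not test chance either. The splits with the highest counts, 1114 above and 4438 below, both kept the Tg+ sham arrays together and mixed only the wild-type arrays.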

How the results depend on the processing

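Leaving out weak-signal arrays, and keeping features above background on all arrays, were chosen after the data had been seen. The latter removes genes that fell, and the former leaves 1 array each in wild-type I/R above and Tg+ I/R below, assumed to vary like the other groups. No weak-signal array is in the comparison for surgery in Tg+ above, so its count moves through the shared spread alone. Counts not given here stayed within 1.5 times the main count, and leaving out the background correction moved none. The cause of a move was not tested, apart from settings that test fewer genes or arrays. With Agilent's log ratio, counts were 1 for genotype in sham above, 1 for genotype in sham below, 13 for genotype after I/R above, 1226 for genotype after I/R below, 317 for surgery in wild type below, 726 for surgery in Tg+ above, 0 for the interaction above, 0 for the interaction below and 50 for location after I/R. With the series value table, counts were 1 for genotype in sham above, 1 for genotype in sham below, 13 for genotype after I/R above, 1228 for genotype after I/R below, 318 for surgery in wild type below, 726 for surgery in Tg+ above, 0 for the interaction above, 0 for the interaction below and 50 for location after I/R. With the Cy5 channel alone, counts were 17 for genotype after I/R above, 1697 for genotype after I/R below, 949 for surgery in wild type above, 844 for surgery in Tg+ above, 0 for the interaction above, 1 for the interaction below and 65 for location after I/R. Without the filter on dim probes, counts were 43 for genotype after I/R above and 80 for genotype after I/R below. With slide as a block, counts were 2 for genotype in sham above, 0 for genotype after I/R below, 259 for surgery in wild type above, 25 for surgery in wild type below, 359 for surgery in Tg+ above, 249 for surgery in Tg+ below, 0 for the interaction above, 0 for the interaction below and 4 for location after I/R. With only the arrays of a comparison, counts were 2 for genotype in sham above, 0 for genotype after I/R above, 0 for genotype after I/R below, 796 for surgery in wild type above, 0 for surgery in wild type below, 3692 for surgery in Tg+ above, 1 for the interaction above and 0 for location after I/R. With array weights, counts were 581 for genotype in sham above, 24 for genotype in sham below, 1283 for genotype after I/R above, 6310 for genotype after I/R below, 4526 for surgery in wild type above, 1941 for surgery in wild type below, 5214 for surgery in Tg+ above, 6195 for surgery in Tg+ below, 1262 for the interaction above, 5132 for the interaction below, 432 for location after I/R and 60 for location by surgery. With the mean of all probes, counts were 20 for genotype after I/R above. Without the weak-signal arrays, counts were 884 for genotype after I/R below, 1343 for surgery in wild type below, 4760 for surgery in Tg+ above, 1547 for surgery in Tg+ below, 49 for the interaction above, 13 for the interaction below, 382 for location after I/R and 248 for location by surgery. With features above background on all arrays, counts were 0 for genotype in sham above, 0 for genotype in sham below, 680 for surgery in wild type above, 303 for surgery in wild type below, 663 for surgery in Tg+ above, 1606 for surgery in Tg+ below, 0 for the interaction above, 0 for the interaction below and 50 for gene lists. With an estimated correlation, counts were 0 for gene lists. Leaving out 1 array, counts ranged over 2 to 4 for genotype in sham above, 760 to 2177 for surgery in wild type above, 2 to 9 for the interaction above, 0 to 0 for location in sham, 0 to 3 for location by surgery, 2 to 2 for genotype in sham below, 263 to 719 for surgery in wild type below, 2 to 2035 for the interaction below, 684 to 1925 for surgery in Tg+ above, 1874 to 4783 for surgery in Tg+ below, 0 to 506 for genotype after I/R above, 11 to 250 for location after I/R, 4 to 5219 for genotype after I/R below and 102 to 140 for gene lists. Array weights came from limma's gene-by-gene method, which it uses when spots are missing. Its REML method stopped before it converged and gave up to 6837 calls. The Trim63 genotype differences ranged over -0.03 to 0.10 in sham above, -0.12 to 0.03 in sham below, -0.18 to 0.24 after I/R above and -1.53 to -0.57 after I/R below when 1 array was left out. After I/R below the difference passed with the Cy5 channel alone (-1.08, adjusted p = 0.0382) and with array weights (-1.78), with adjusted p from 8.83e-06 to 0.658 over all settings. Of 421 gene results, calls were lost for 300 with the slide block, 115 with Agilent's log ratio, 102 without the filter, 143 with only the arrays of a comparison, 95 with the Cy5 channel alone and 85 without the weak-signal arrays, and 1 turned its sign: Acta2 in Tg+ above, at 0.13 with the mean of all probes. Agilent's log ratio moved the median of all genes by -0.17, -0.21 and -0.24 for surgery in wild type above, wild type below and Tg+ below, so its changes are relative to those shifts. The share of higher calls after I/R between pieces went from 45% to 30% with it. Replicate numbers do not pair the samples by the rule used: 8 of 12 pairs of pieces with the same number correlated above 0.1 (all 6 in Tg+ hearts, and 2 of 6 in wild type) and 7 arrays correlated best with their own number. With the replicate number or heart as a block the count for genotype after I/R below was 148. No other total moved by over 1.5 times with that block, although higher calls between pieces after I/R went from 9 to 17 and those for genotype after I/R above from 29 to 18. On the weakest array 9.90% of Cy5 spots were well above background, which limits what it can show.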

Other observations

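Cardiomyocyte share and slide differences were tested, and leaving out weak arrays was chosen, only after results had been seen. Tests called set beforehand were set after the pattern was seen but before their own values were computed. Several responses of I/R hearts fell outside the main lists. The fetal and stress list had medians of 0.52 in wild type and 0.66 in Tg+ below the site, and 3 (3 higher and 0 lower adjusted over the list alone, adjusted p = 0.0002, and adjusted p = 0.353 with an estimated correlation) and 7 (7 higher and 0 lower adjusted over the list alone, adjusted p = 0.00192, and adjusted p = 0.449 with an estimated correlation) of its 18 members rose there. Of 19 heat shock genes 4 rose and 7 fell in Tg+ hearts below (5 higher and 9 lower adjusted over the list alone, adjusted p = 0.366, and adjusted p = 0.726 with an estimated correlation). Hspb1 rose (1.43 ± 0.29), and Hspb8 (-1.33 ± 0.31) and Bag3 (-1.23 ± 0.25) fell. Glycolysis genes Pfkm and Pfkl fell in all 4 surgery comparisons (Pfkm between -1.20 and -0.76, Pfkl between -0.51 and -0.31). The Pfkl call was lost in 3 of 6 fits that left out an array in wild type below (adjusted p up to 0.0739) and in 1 of 6 in Tg+ above (up to 0.0522). In wild type above the glucose transporter Slc2a1 rose by 0.91 ± 0.22.

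Mitochondrial lists had medians below 0 in Tg+ against wild type below the site after I/R, with 8 of 34 oxidative phosphorylation genes (adjusted p = 0.486 with an estimated correlation) and 5 of 29 fatty acid oxidation genes (adjusted p = 0.553 with an estimated correlation) past the threshold, and weak Cy5 signal is a candidate source that stays open. The test set beforehand gave r = -0.52 between the mean oxidative phosphorylation ratio and the share of Cy5 spots above background over the 12 I/R arrays (permutation p = 0.0815, adjusted p = 0.122, rho = -0.28 with p = 0.375, r = -0.40 without the 2 farthest arrays), and an r under 0.3 was to exclude it. That bound assumed that weak arrays all move one way, which the values deny: the weakest wild-type array had a mean of 2.57 and the weak Tg+ arrays 1.68 and 1.36, and the fatty acid oxidation difference was 0.05 without the weak arrays. Of the 10 splits of the 6 arrays, the one that put the 3 weak arrays together gave 5930 genes against 314 for the genotypes, which is too few splits for a share under 0.05. A lower share of cardiomyocytes stays open too (9 of 9 other cell type lists had medians above 0, but from 0.11 to 0.66, and from 0.04 to 0.63 without the weak arrays), as do slide differences (mean shift -0.34 with slide as a block), and a genotype effect remains among the open explanations. With slide as a block the mean shift of smooth muscle and pericyte markers went from 0.08 to -0.11, while those of the other cell type lists stayed above 0.

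The atrial markers had a median of -0.74 below against above in I/R hearts, with 1 of 12 past the threshold over all genes (adjusted p = 0.312 for the list with an estimated correlation), and more atrial tissue in some pieces is a candidate explanation. The mean of the other atrial markers followed Myl7 over the 6 I/R arrays above with r = 0.86, past the bound set beforehand (exact permutation p = 0.0486, adjusted p = 0.122, rho = 0.60 with p = 0.242), but rests on 2 arrays, without which r was -0.37, so the explanation stays open. The 4 arrays behind that r had Myl7 between 4.62 and 5.34, too narrow a range to test the link. Among sham pieces above, Myl7 was 2.67 in wild-type replicate 3 and 4.28 in Tg+ replicate 2 and between -2.35 and -1.13 in the other 4. The mean of the other atrial markers was 0.14 and 0.70 in these 2 pieces and between -0.44 and -0.32 in the other 4, so it went with Myl7 without I/R too. Weak Cy5 signal is argued against, since without the weak arrays the Myl7 difference was -7.35 ± 1.31 against -5.61 ± 1.04 with all. Whether atria were kept is not given in the sources used here, and an effect of injury on these transcripts was not tested apart from it.

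Splits of the same arrays were counted for every comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each comparison except genotype below after I/R (2 of 10). The real count and the highest other were 4 and 0, and 3 and 0, for genotype in sham hearts above and below, and 75 and 2 for genotype above after I/R. For surgery they were 1520, 642, 1745 and 3699, each against 0. Among 100 splits of location labels, 17 gave as many genes as the 20 in I/R hearts (highest other 5813), as did 10 of the 76 that kept the real grouping of neither genotype, so chance is not excluded for that count. These splits move pieces between hearts, because the labels do not say which pieces share a heart. Counts of 0, in sham hearts (highest other 0) and for the difference between surgeries (highest other 3213), cannot be tested this way, since all 100 splits must give as many.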
